A study of Mus musculus with 12 samples.

How the data were processed

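Gastrocnemius muscle RNA from 12 mouse samples was measured by RNA sequencing, 3 each of naive, saline-injected, bupivacaine-injured and bupivacaine-injured then needled muscle, groups that the sample titles name wild type, sham, injury and acupuncture. Per the labels' protocols, total RNA was extracted with Trizol and made into libraries with a NEBNext Ultra kit. The labels gave no date, batch or collection time, and did not say whether each sample came from a separate animal.

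The deposited count table holds whole-number counts per gene, 1 column per sample. Per the submitters' processing notes reads were aligned with HISAT2 2.0.5 to the mouse genome mm10. The counting tool, annotation and filters were not given in the sources used here. The deposited FPKM table holds FPKM values per gene, per its name as the authors deposited it. Count divided by FPKM, relative to naive replicate 1, was constant across genes within each sample (6831 genes compared, 100% within 1e-6 of the mean on the log scale). After rounding, this scale per sample equalled median-ratio size factors of the counts and not column totals. The FPKM values served an alternative test alone. Of 54532 counted gene IDs, 54495 had a symbol in GENCODE M21, from which coordinates on mm10 were also taken. Genes that share reads with near-identical copies cannot be told apart here. For that reason or for an overlapping gene, mt-Co2 and mt-Nd4l, which the naming rule took, were left out of the named examples. They stayed in the mitochondrially encoded list, its counts and its tests.

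Total counts per library lay between 16385233 and 27155738. The main test was edgeR 4.0.16's quasi-likelihood test in R 4.3.3 on the deposited counts, with TMM scaling, edgeR's filter on low counts by group, robust dispersion and 1 fit of all 12 libraries with a mean per group. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed, two-sided. The filter kept 15715 genes. Values per group are TMM-scaled CPM, and list scores and principal components use log2 CPM with a prior count of 2. Comparisons were saline against naive, injury against saline, needling against injury and needling against saline.

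Gene lists, 31 in all, were fixed before the data were examined, as were the comparisons, the other settings to try and the rule for naming genes. They cover muscle fibres and their metabolism (fast, slow, embryonic, oxidative phosphorylation, fatty acid oxidation, glycolysis, mitochondrially encoded genes), myogenic regulators, immune cells and their signals (neutrophil, macrophage, lymphocyte, mast cell, cytokine, complement, interferon), matrix, progenitor, endothelial, pericyte, nerve, tendon, fat, blood, skin, cell division, denervation, neuromuscular junction, growth factor, circadian, heat shock and immediate early genes. Each was tested with camera and fry of limma 3.58.1, camera with a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison. Counts of members were also adjusted over the list alone.

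The naming rule took, per comparison, the 8 genes with the largest increase and the 8 with the largest decrease among protein-coding genes that passed, did not overlap between groups and reached 5 CPM in the higher group. From each described list it took up to 4 members with the smallest adjusted p, or, where none passed, up to 2 with the highest CPM. Which of these genes the text names was chosen after their values were seen. Myf6 and Actc1 were left out of needling against injury after their sign was seen to change between settings. Their log2 differences in the 12-library fit were 0.11 and -0.02.

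The correlation of injury with needling effects used fold changes of comparisons that share no library. Chance values came from 20 simulated sets of unchanged groups. Whether replicate numbers pair the samples was tested by the correlation of deviations from group means. Same-numbered injury and needling libraries correlated at 0.238, 0.485 and 0.422, over the 0.1 that the criterion asks of each pair, while no other pair of groups met it. Saline and needling libraries correlated at 0.216, 0.176 and 0.0413 by number, and naive and saline libraries at 0.0672, 0.111 and 0.0822. In both of these, each library correlated best with its own number. The labels give no origin for the pairing of injury with needling libraries. A replicate block for the 6 injury and needling libraries, and 1 for the same libraries within the fit of 12, were added after seeing the data.

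The other settings were DESeq2 1.42.0, median-ratio size factors, no filter (30008 genes) and a stricter filter on low counts (13985 genes), a replicate block over 12 libraries, the 2 groups alone, limma on log2(FPKM + 1) and log2(FPKM + 0.1), limma-voom with quality weights, a 2-fold minimum, naive as the control and leaving out each library. The steps were tested on simulated counts drawn from the real means, with 100 genes changed 2-fold and 100 changed 4-fold. For injury against saline 60 and 91 were recovered among 15412 genes, and 10 unchanged genes were called. For needling against injury 68 and 97 were recovered among 15404 genes, and 9 unchanged genes were called. With the 6-library block 58 and 96 were recovered among 15314 genes, and 15 unchanged genes were called. Simulated genes vary independently, which real genes do not, and the block was not chosen from the simulated counts as it was from the real ones.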

Results

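Messenger RNA was sequenced from the gastrocnemius, a calf muscle rich in fast-contracting fibres, of wild-type C57BL/6 mice aged 6 to 7 months. The 12 libraries fell into 4 groups of 3. Naive muscle was left uninjected, and saline muscle received the vehicle injection alone. Injury muscle was injected with bupivacaine, a local anaesthetic that destroys muscle fibres while sparing much of the resident stem cell pool. Needling muscle received bupivacaine and then acupuncture 24 hours later. Total gene counts per library ranged from 16385233 in saline replicate 1 to 27155738 in injury replicate 3. Mitochondrially encoded genes took between 7.12% and 13.5% of the counts, and the 10 most abundant genes between 14.0% and 24.8%. The labels did not state that the replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical. Tissue collection times were not given in the sources used here.

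The first principal component of log2 CPM held 62.6% of the variance and ordered the groups from naive through saline and injury to needling. Naive libraries lay between -79.97 and -50.04 on it, saline between -50.25 and -21.82, injury between 6.01 and 39.1, and needling between 53.4 and 82.6. Naive replicate 1 stood apart on the second component, at 62.3, where the other 11 libraries lay between -15.83 and 7.31. That library also held high transcripts of heat shock chaperones. Hspa1a, an inducible chaperone gene chosen after its values were seen, measured 2060 CPM there and at most 37.8 CPM in the other 11 libraries.

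**Figure D1:**
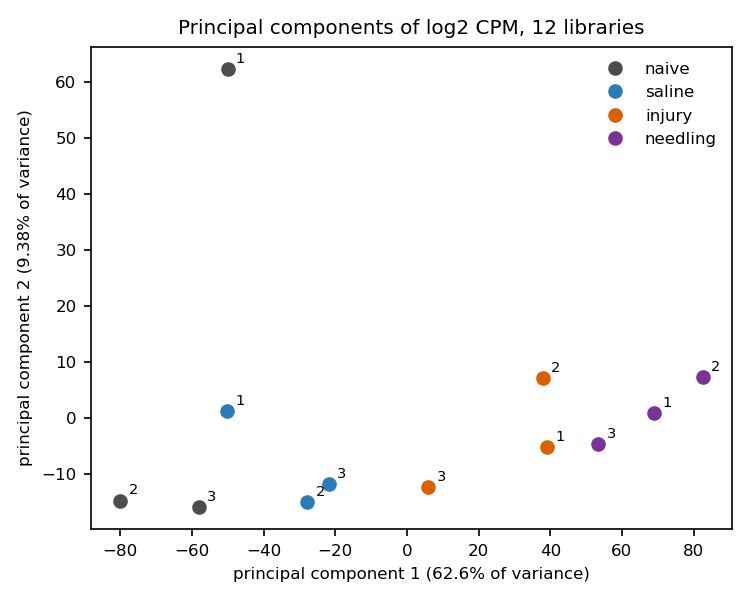
Principal components of log2 CPM in the 12 libraries, with component 1 (62.6% of variance) on the horizontal axis and component 2 (9.38%) on the vertical axis, both in log2 units. Each point is a library numbered by replicate and coloured by group. All 3 needling libraries lie at 53.4 or above on component 1, and naive replicate 1 lies at 62.3 on component 2.

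The comparison of saline with naive muscle asked what the injection itself did. No gene passed the threshold. Many macrophage and connective tissue genes had higher estimates in saline muscle, but no list passed camera with an estimated correlation. Lyz2, which encodes the lysozyme of macrophages and monocytes, measured 58.2 ± 15.3 CPM in naive and 169 ± 77.4 CPM in saline muscle (SD, n = 3), a log2 difference of 1.54 ± 0.36 (SE; edgeR quasi-likelihood adjusted p = 0.27). Col3a1, a fibrillar collagen gene, measured 178 ± 23.5 and 361 ± 59.7 CPM (SD, n = 3), a log2 difference of 1.02 ± 0.20 (SE; edgeR adjusted p = 0.255). The estimate of mt-Co1, a mitochondrially encoded subunit of cytochrome oxidase, was lower without passing, at 50850 ± 10500 CPM in naive and 35240 ± 4490 CPM in saline (SD, n = 3; log2 difference -0.53 ± 0.25; edgeR adjusted p = 0.43).

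Of 22 measured macrophage and monocyte genes, 21 had higher estimates in saline and 14 passed when adjusted over the list alone, while none passed among all genes tested. The extracellular matrix list had 23 of 27 members with higher estimates, of which 15 passed adjusted over the list alone, with Sparc at 206 ± 8.69 CPM in naive and 326 ± 60.0 CPM in saline muscle (SD, n = 3). Of 11 complement genes all 11 had higher estimates and 8 passed adjusted over the list alone. Complement component C3 measured 66.1 ± 17.0 CPM in naive and 128 ± 20.4 CPM in saline muscle (SD, n = 3). All 13 markers of fibro-adipogenic progenitors, the connective tissue precursors of muscle, had higher estimates, with 7 passing adjusted over the list alone. All 6 mast cell genes had higher estimates, and none passed adjusted over the list alone. All 21 oxidative phosphorylation genes and 12 of 13 mitochondrially encoded genes had lower estimates, and none of them passed adjusted over the list alone. These lists passed camera with its preset correlation of 0.01, at adjusted p = 2.07e-14 for macrophages, 2.12e-14 for matrix, 9.47e-10 for complement, 5.5e-09 for progenitors, 0.00135 for mast cells, 4.02e-09 for oxidative phosphorylation and 2.43e-06 for mitochondrially encoded genes. With an estimated correlation the adjusted p was 0.386, 0.381, 0.245, 0.381, 0.519, 0.519 and 0.519 in that order. Of 24 cell division genes 23 had higher estimates and 8 adjusted over the list alone (camera adjusted p = 6.03e-11 with the preset and 0.465 with an estimated correlation). For the cell division and macrophage lists 1 saline library stood with naive muscle. Saline replicate 1 had a cell division score of 0.31 (mean log2 CPM of the list), against -0.22 to 0.28 in naive and 1.44 and 1.68 in the other 2 saline libraries. Its macrophage score of 1.96 lay within the naive range of 1.14 to 2.30. All 10 slow fibre genes had lower estimates and none passed adjusted over the list alone (camera adjusted p = 0.00101 with the preset and 0.653 with an estimated correlation). This came from saline replicate 1, with a slow fibre score of 3.36 against 7.45 and 7.00 in the other 2, and without it the camera adjusted p was 0.452.

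The heat shock list lay lower in saline muscle (camera adjusted p = 0.0067 with the preset correlation and 0.715 with an estimated correlation), and this difference came from naive replicate 1. Without that library the list lay in the opposite direction by limma's camera (adjusted p = 0.0689), and the log2 difference of the chaperone gene Hspa8 turned from -0.75 to 0.12 and that of Cryab from -1.08 to 0.07.

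By edgeR's quasi-likelihood test 0 of 15715 genes differed between saline and naive muscle at an adjusted p under 0.05, with a smallest adjusted p of 0.229 and 1865 genes at an unadjusted p under 0.05. DESeq2 called 152 genes, 128 higher and 24 lower in saline. Leaving out saline replicate 1 gave 25 genes, leaving out naive replicate 3 gave 13 and leaving out naive replicate 1 gave 1.

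Comparing injury with saline muscle asked what bupivacaine added to the injection. Genes of cell division, macrophages and matrix were among those that rose after bupivacaine, as were some genes of embryonic and denervated muscle. No list passed camera with an estimated correlation. Cdk1, the kinase that drives entry into mitosis (ENSMUSG00000019942, chromosome 10, 69335146 to 69352938, mm10), rose from 0.794 ± 0.62 CPM in saline to 6.14 ± 2.67 CPM in injury muscle (SD, n = 3), a log2 fold change of 2.88 ± 0.46 (SE; edgeR adjusted p = 0.0106). Myog, the transcription factor of differentiating myoblasts (ENSMUSG00000026459, chromosome 1, 134289989 to 134292548), rose from 12.8 ± 5.98 to 57.6 ± 26.7 CPM (SD, n = 3; log2 fold change 2.17 ± 0.48; edgeR adjusted p = 0.036). Adgre1, which encodes the macrophage surface protein F4/80 (ENSMUSG00000004730, chromosome 17, 57358691 to 57483527), rose from 8.25 ± 3.29 to 28.5 ± 8.09 CPM (SD, n = 3; log2 fold change 1.78 ± 0.31; edgeR adjusted p = 0.0151). Altogether 669 of 15715 genes passed, of which 658 were higher and 11 lower in injury muscle.

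Among the genes taken by the fixed rule for size, the largest increases were those of the macrophage elastase gene Mmp12, at a log2 fold change of 3.11, and of Atp6v0d2, a proton pump subunit, at 3.03. Cthrc1, a secreted protein of activated fibroblasts, followed at 3.01, and Chrng, the fetal subunit of the acetylcholine receptor, at 3.00. The mitotic cyclin gene Ccnb1 rose by 2.99 and Msln, which encodes mesothelin, by 2.94. Mymk, whose product fuses myoblasts, rose from 1.82 ± 1.61 to 14.3 ± 8.22 CPM (SD, n = 3), a log2 fold change of 2.94. The decreases that the rule took were smaller. Of all 11 lower genes 4 fell at least 2-fold, and the rule took none of these. Igfals, which encodes a carrier of insulin-like growth factors, changed by -0.93, Cadm4 by -0.85 and Neto2 by -0.74 on the log2 scale. Tmem94 changed by -0.41 and Mif4gd by -0.39. With Cdk1, these 13 genes had an edgeR adjusted p between 0.0106 and 0.0441.

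Of the 24 measured cell division genes 18 rose and none fell, 23 passing when adjusted over the list alone, and Bub1 and Plk1 gained 3.16 and 2.66 on the log2 scale. Of the 22 macrophage and monocyte genes 9 rose, 21 adjusted over the list alone. The mannose receptor gene Mrc1 increased from 22.1 ± 3.76 to 42.7 ± 8.27 CPM (SD, n = 3), the lysozyme gene Lyz2 from 169 ± 77.4 to 618 ± 174 CPM, and the complement component gene C1qb from 31.4 ± 10.3 to 90.4 ± 22.3 CPM. The extracellular matrix list had 8 of 27 members higher, 15 adjusted over the list alone. They included Fn1, which encodes fibronectin, from 114 ± 17.5 to 227 ± 40.5 CPM, Col3a1 from 361 ± 59.7 to 709 ± 183 CPM, and Col5a2 and Tgfbi at log2 fold changes of 1.04 and 0.91. Camera passed these lists with the preset correlation, at adjusted p = 4.51e-34, 2.63e-22 and 1.48e-10. With an estimated correlation the adjusted p was 0.173 for cell division, 0.281 for macrophages and 0.462 for matrix. Limma's rotation test fry, which asks whether the genes of a list move one way on balance, gave adjusted p = 0.0186, 0.0375 and 0.0835.

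Muscle regeneration genes moved in part. Of 15 satellite cell and myogenic regulator genes 2 passed, Myog and Mymk, and 6 passed adjusted over the list alone. Of 12 embryonic and regenerating fibre genes 4 passed, namely Chrng, the cardiac troponin gene Tnnt2 at a log2 fold change of 2.12 ± 0.39 (SE), the embryonic light chain gene Myl4 at 1.94 ± 0.38 and the adhesion molecule gene Ncam1 at 1.02 ± 0.26. Of 15 atrophy and denervation genes 2 passed, among them the acetylcholine receptor gene Chrna1, known to rise in denervated muscle, at 1.36 ± 0.22. For these 3 lists camera gave adjusted p = 0.000411, 0.000447 and 0.0245 with the preset correlation and 0.535, 0.462 and 0.535 with an estimated correlation. Without injury replicate 2 the denervation list did not pass (adjusted p = 0.0537 with the preset correlation). Among 18 interferon response genes 2 rose, Mx1 and Rsad2, and 9 passed adjusted over the list alone (camera adjusted p = 8.87e-08 with the preset and 0.535 with an estimated correlation). Among complement genes 3 of 11 rose. These were C3ar1, C5ar1 and the integrin gene Itgb2, all of which encode receptors of leukocytes. Of 19 growth factor genes 3 rose, Tgfb1, Hgf and Gdf15, while the list had a mean log2 difference of 0.25 and a median of -0.10 and did not pass camera (adjusted p = 0.763 with the preset and 0.863 with an estimated correlation). The tendon transcription factor gene Scx rose from 7.35 ± 1.28 to 14.5 ± 3.50 CPM (SD, n = 3) as the only 1 of 10 tendon genes, a list whose mean log2 change was -0.36. Of 19 cytokine and chemokine genes 1 passed, Ccl3, at a mean of 0.969 CPM in injury muscle.

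Genes of mature fibres did not pass singly. Of 17 fast fibre genes 15 had lower estimates in injury muscle and none passed. The fast myosin gene Myh4 measured 44510 ± 8530 CPM in saline and 32520 ± 6140 CPM in injury muscle (SD, n = 3; log2 difference -0.45 ± 0.27; edgeR adjusted p = 0.458). The skeletal actin gene Acta1 measured 30900 ± 2000 and 26400 ± 2990 CPM (SD, n = 3; edgeR adjusted p = 0.647). All 21 oxidative phosphorylation genes had lower estimates, with a mean log2 difference of -0.18, and none passed. Of 17 glycolysis and glycogen genes 16 had lower estimates and none passed. As lists these lay lower by camera, at adjusted p = 0.00103 for fast fibres, 0.0149 for oxidative phosphorylation and 2.25e-06 for glycolysis with the preset correlation. With an estimated correlation the adjusted p was 0.589, 0.708 and 0.535. The oxidative phosphorylation list did not pass with the preset correlation without saline replicate 2 (adjusted p = 0.369), saline replicate 3 (0.0648) or injury replicate 2 (0.067).

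The count of 669 depended on single libraries. It was 0 without injury replicate 1, 74 without injury replicate 2, 1098 without injury replicate 3, 103 without saline replicate 1, 161 without saline replicate 2 and 428 without saline replicate 3. Injury replicate 3 lay nearest to saline on the first principal component, at 6.01, and its macrophage score of 4.38 (mean log2 CPM of the list) was below the 5.15 and 5.37 of the other 2. DESeq2 called 1036 genes and limma-voom with quality weights 1107. With naive in place of saline as the control 2796 genes passed, 1926 higher and 870 lower.

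**Figure D2:**
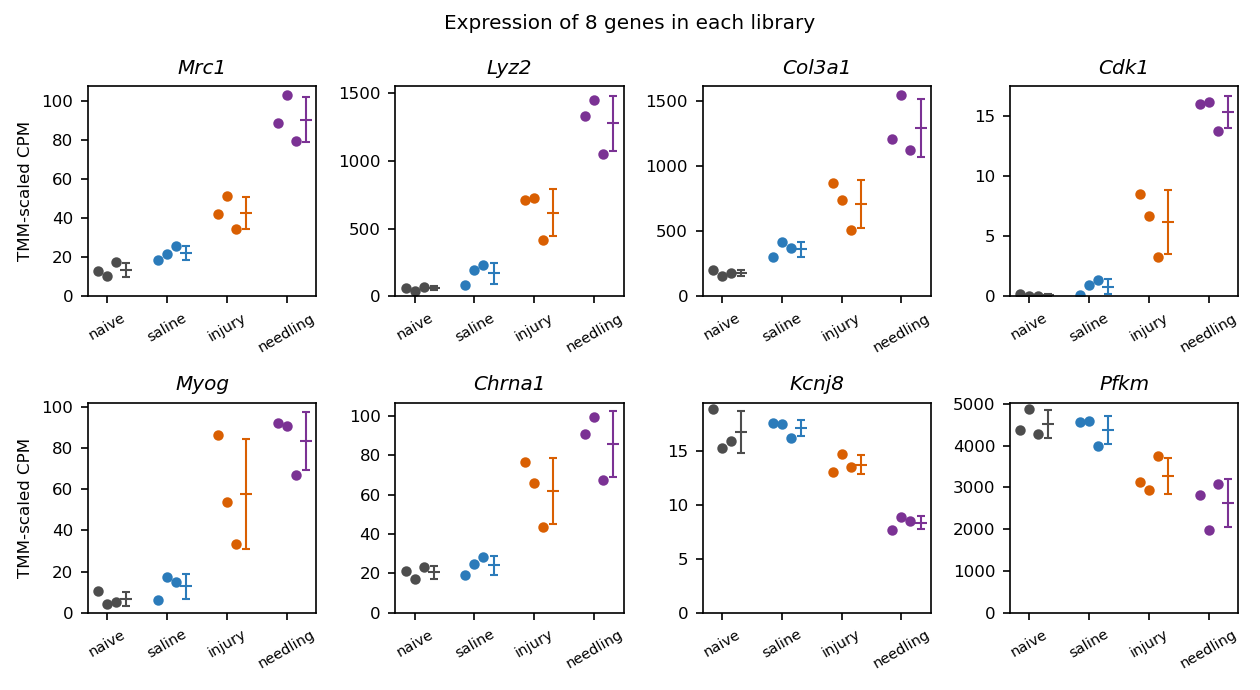
TMM-scaled CPM of 8 genes on linear axes from 0 in each of the 12 libraries, by group. Points are libraries, and the bar beside them is the mean ± SD of 3 libraries. Mrc1 averages 13.6, 22.1, 42.7 and 90.5 CPM in naive, saline, injury and needling muscle, and Kcnj8 averages 16.7, 17.1, 13.7 and 8.33 CPM.

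The comparison the series was built around set needled injured muscle against injured muscle without needling. No gene passed the threshold in the fit of all 12 libraries, and no list passed fry or camera with an estimated correlation. Estimates of macrophage, cell division and matrix genes were higher and those of energy metabolism genes lower in the needling group. Lyz2 measured 618 ± 174 CPM in injury and 1278 ± 203 CPM in needling muscle (SD, n = 3), a log2 difference of 1.05 ± 0.35 (SE; edgeR adjusted p = 0.17). Col3a1 measured 709 ± 183 and 1294 ± 222 CPM (SD, n = 3; log2 difference 0.87 ± 0.20; edgeR adjusted p = 0.102). Pcna, the sliding clamp of DNA replication, measured 37.2 ± 7.63 and 57.8 ± 11.1 CPM (SD, n = 3; log2 difference 0.64 ± 0.18; edgeR adjusted p = 0.114). Vegfa, which encodes the main vascular growth factor, measured 210 ± 12.8 and 148 ± 18.1 CPM (SD, n = 3; log2 difference -0.50 ± 0.12; edgeR adjusted p = 0.102).

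By edgeR's quasi-likelihood test 0 of 15715 genes differed between needling and injury muscle, with a smallest adjusted p of 0.0971, 61 genes under 0.10 and 2606 genes at an unadjusted p under 0.05, of which 2021 were higher in needling. Other tools and fits disagreed on this count. DESeq2 called 567 genes (533 higher, 34 lower), limma-voom with quality weights 911 (806 higher, 105 lower), limma on log2(FPKM + 1) 161 and edgeR without a filter on low counts 49. Limma on log2(FPKM + 0.1), edgeR with median-ratio size factors, with a stricter filter, with the 2 groups alone and with the replicate number as a block across all 12 libraries each called 0. Leaving out needling replicate 3 gave 1 gene.

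Same-numbered injury and needling libraries deviated together from their group means, so that the replicate numbers pair these samples by the criterion set out in the processing. A fit of the 6 libraries alone with the replicate number as a block was therefore added, after the fits above had been seen. It called 3041 genes, 1931 higher and 1110 lower in needling muscle, but it estimates the spread from 2 residual degrees of freedom per gene. Keeping all 12 libraries and blocking the injury and needling libraries alone, which was also added after seeing the data, gave 373 genes, 357 higher and 16 lower. Of these 373 genes, 371 were among the 3041, as were 559 of the 567 genes of DESeq2. The count of changed genes between needling and injury muscle therefore ranged from 0 to 3041 with the fit. The pairing behind the highest value came from the data and not from the labels. The p-values of both blocked fits do not take in that choice of pairing from the same data, so they may be too small.

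The protein-coding genes with the smallest p in the 6-library blocked fit, chosen after their values were seen, included Trem2, Tyrobp and Mrc1. Trem2, a lipid-sensing receptor of phagocytes, measured 26.6 ± 8.19 CPM in injury and 61.5 ± 14.6 CPM in needling muscle when scaled over these 6 libraries (SD, n = 3), a log2 fold change of 1.23 ± 0.08 (SE; edgeR adjusted p = 0.00023 with the block). Its adaptor gene Tyrobp had a log2 fold change of 1.06 ± 0.07 and Mrc1 one of 1.06 ± 0.07, with an edgeR adjusted p of 0.000261 for both with the block. The complement gene C1qb had a log2 fold change of 1.09 and the platelet factor gene Pf4, which tissue macrophages also express, one of 1.07.

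By lists, all 22 macrophage and monocyte genes had higher estimates in needling muscle with a median log2 difference of 1.03, and 6 passed adjusted over the list alone without the block. With the block in the 6 libraries, 21 of 22 rose among all genes tested. All 24 cell division genes had higher estimates with a mean of 0.92, and 21 passed adjusted over the list alone. With the block 23 rose, among them Mcm2, a subunit of the replicative helicase, and Pcna. All 27 matrix genes had higher estimates with a mean of 0.67, 17 passed adjusted over the list alone, and 16 rose with the block, among them Col3a1 and Sparc. All 10 tendon genes had higher estimates, 1 passed adjusted over the list alone and 4 rose with the block, one of them the matricellular gene Thbs4. Of 19 cytokine and chemokine genes 18 had higher estimates, none passed adjusted over the list alone, and 6 rose with the block. Osteopontin, encoded by Spp1, measured 292 ± 237 CPM in injury and 549 ± 313 CPM in needling muscle (SD, n = 3), a log2 difference of 0.91 ± 0.99 (SE) without the block and 1.09 ± 0.18 with it, where it passed (edgeR adjusted p = 0.0106).

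All 21 oxidative phosphorylation genes had lower estimates in needling muscle with a mean log2 difference of -0.33, and 15 fell with the block. The ATP synthase genes Atp5b and Atp5a1, at -0.31 and -0.33, passed in neither fit. All 18 fatty acid oxidation genes had lower estimates, 10 falling with the block, and the fatty acid binding protein gene Fabp3 measured 581 ± 74.9 CPM in injury and 384 ± 144 CPM in needling (SD, n = 3) and passed in neither fit. The difference of this list was uneven over same-numbered pairs, at -0.828, -0.358 and -0.143 log2 units for replicates 1, 2 and 3. That of the glycolysis list was 0.00183, -0.501 and -0.52. Needling replicate 1 had a low slow fibre score of 5.46. The other needling libraries had 7.11 and 7.14, and injury libraries lay between 6.81 and 7.25. All 17 fast fibre genes and all 17 glycolysis and glycogen genes had lower estimates, and 1 and 3 of them fell with the block. The glycogen phosphorylase gene Pygm, with a log2 difference of -0.31, passed in neither fit. All 13 mitochondrially encoded genes had lower estimates, 2 falling with the block. All 12 endothelial genes had lower estimates, 5 falling with the block, among them the receptor gene Flt1 (log2 difference -0.43), and of 10 pericyte and smooth muscle genes 7 had lower estimates and 3 passed adjusted over the list alone, among the lower ones Rgs5 (log2 difference -0.47), which fell with the block. Of the 15 myogenic regulator genes all 15 had higher estimates with a mean of 0.29, none passed adjusted over the list alone, and 2 rose with the block. The myogenic integrin gene Itga7 had a log2 difference of 0.21 and passed in neither fit. Interferon response genes went both ways, 10 of 18 with higher estimates, and 2 rose with the block. Bst2 measured 20.3 ± 6.63 CPM in injury and 34.8 ± 18.0 CPM in needling muscle (SD, n = 3) and rose with the block (edgeR adjusted p = 0.00285), while Irgm1 measured 19.2 ± 1.41 and 16.7 ± 3.21 CPM and passed in neither fit.

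Without the block, camera with the preset correlation passed 13 of 31 lists, 5 up and 8 down. Its adjusted p was 5.26e-10 for macrophages, 5.06e-14 for cell division, 7.89e-12 for matrix, 0.00275 for tendon, 0.016 for cytokines, 2.46e-08 for oxidative phosphorylation, 3.05e-07 for fatty acid oxidation, 8.44e-05 for fast fibres, 4.41e-05 for glycolysis, 9.26e-07 for mitochondrially encoded genes, 0.000368 for endothelium, 0.00222 for pericytes and 0.0223 for erythroid genes. With an estimated correlation no list passed, at adjusted p = 0.542 for macrophages, cell division, matrix, tendon, oxidative phosphorylation, fatty acid oxidation, fast fibres, glycolysis, mitochondrially encoded genes and pericytes, 0.565 for endothelium, 0.64 for erythroid genes and 0.707 for cytokines. The cytokine list did not pass with the preset correlation without injury replicate 1 (adjusted p = 0.0569), injury replicate 3 (0.053) or needling replicate 2 (0.126), nor the erythroid list without injury replicate 3 (0.31). Fry passed no list, its smallest adjusted p being 0.167. In the 6-library fit with the block 20 lists passed the preset camera, 11 up and 9 down, and none passed with an estimated correlation (adjusted p = 0.534 for macrophages, cell division, matrix and oxidative phosphorylation).

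**Figure D3:**
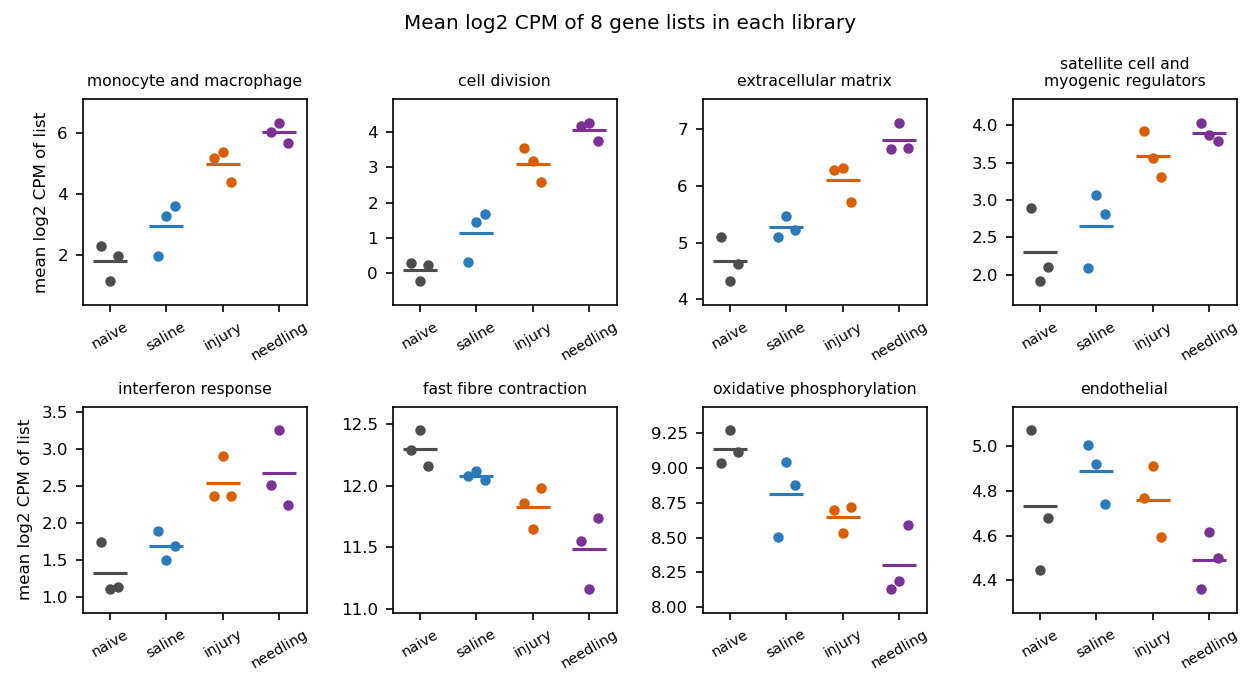
Mean log2 CPM over the measured members of 8 gene lists in each of the 12 libraries, by group. Points are libraries and lines are means of 3 libraries, and each panel has its own axis range, which does not start at 0. The macrophage score lies between 4.38 and 5.37 in injury and between 5.67 and 6.32 in needling libraries, and the oxidative phosphorylation score of needling replicate 3, at 8.59, lies within the injury range of 8.53 to 8.72.

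Needled injured muscle set against saline muscle showed the full distance from the vehicle injection. Here 4647 of 15715 genes passed, 2915 higher and 1732 lower in needling muscle. Mrc1 (ENSMUSG00000026712, chromosome 2, 14229392 to 14332057, mm10) rose from 22.1 ± 3.76 to 90.5 ± 11.8 CPM (SD, n = 3), a log2 fold change of 2.03 ± 0.20 (SE; edgeR adjusted p = 8.06e-05). Cdk1 rose from 0.794 ± 0.62 to 15.3 ± 1.34 CPM (SD, n = 3; log2 fold change 4.20 ± 0.45; edgeR adjusted p = 8.66e-05). The muscle glycolytic enzyme gene Pfkm fell from 4378 ± 341 to 2626 ± 580 CPM (SD, n = 3; log2 fold change -0.74 ± 0.18; edgeR adjusted p = 0.00958). Kcnj8, a potassium channel gene of pericytes, fell from 17.1 ± 0.751 to 8.33 ± 0.586 CPM (SD, n = 3; log2 fold change -1.03 ± 0.12; edgeR adjusted p = 0.000104).

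Among the largest increases taken by the rule, Spp1 rose from 13.9 ± 12.5 to 549 ± 313 CPM (SD, n = 3), a log2 fold change of 5.30 ± 1.19 (SE). Il1rn, which encodes the interleukin-1 receptor antagonist, gained 5.19 ± 1.38, and Chil3, a chitinase-like gene of alternatively activated macrophages, 4.50 ± 1.47. The lectin receptor genes Clec4n and Clec4d gained 4.36 each and the interleukin-7 receptor gene Il7r 4.27. Cthrc1 gained 4.30 and Galnt6, a glycosyltransferase gene, 4.22. Among the decreases, the Schwann cell gene Prx changed by -1.21 ± 0.29. The leptin gene Lep changed by -1.30 ± 0.43, the spermine oxidase gene Smox by -1.29 ± 0.23, Igfals by -1.26 ± 0.24 and the calcium channel subunit gene Cacna2d4 by -1.22 ± 0.37. Lep measured 11.8 ± 4.50 CPM in saline and 4.74 ± 1.89 CPM in needling muscle, which lay near the 5.41 ± 2.64 CPM of naive muscle (SD, n = 3).

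All 22 macrophage genes, 23 of 24 cell division genes and 21 of 27 matrix genes rose (22, 24 and 22 adjusted over the list alone), with mean log2 changes of 2.94, 2.82 and 1.55. Adgre1 gained 2.91 ± 0.32 (SE), C1qb 2.63 ± 0.31, Ccnb1 4.21 ± 0.39, the helicase gene Mcm6 2.37 ± 0.25, Fn1 1.87 ± 0.21 and Col3a1 1.84 ± 0.21. Of 8 neutrophil genes 4 rose, among them the growth factor receptor gene Csf3r from 0.703 ± 0.532 to 7.60 ± 1.77 CPM (SD, n = 3). Of 15 myogenic regulator genes 9 rose, among them Myog at a log2 fold change of 2.70 ± 0.49, Mymk at 3.31 ± 0.69 and the satellite cell cadherin gene Cdh15 at 0.73 ± 0.16. Of 12 embryonic fibre genes 5 rose, among them Tnnt2 at 2.53 ± 0.39 and Chrng at 3.51 ± 0.65. Of 18 interferon response genes 10 rose, among them Oas1a and Irf7 at 2.48 ± 0.42 and 1.99 ± 0.43. Of 15 heat shock and unfolded protein genes 1 rose, the endoplasmic reticulum chaperone gene Hspa5, by 0.56 ± 0.13. Chrna1 rose by 1.83 ± 0.22, C3ar1 by 3.31 ± 0.45, Tgfb1 by 2.15 ± 0.25 and the progenitor marker Mfap5 by 1.06 ± 0.17.

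Members of fibre, metabolism and vessel lists were among the 1732 genes that fell. CPM are relative to the other transcripts of a library, so these falls cannot be told apart here from a changed mix of cells. Of 17 glycolysis and glycogen genes 16 fell, among them Pgam2 at -0.66 ± 0.15 (SE). Of 21 oxidative phosphorylation genes 15 fell, among them Cox7a1 at -0.76 ± 0.19 and the cytochrome c gene Cycs at -0.48 ± 0.12. Of 17 fast fibre genes 9 fell, among them the troponin genes Tnni2 and Tnnt3 at -0.68 ± 0.19 and -0.69 ± 0.20 and the calcium release channel gene Ryr1 at -0.69 ± 0.21. Of 18 fatty acid oxidation genes 3 fell, among them Acadm and the coactivator gene Ppargc1a at -0.66 ± 0.22 and -0.70 ± 0.16. Of 13 mitochondrially encoded genes 7 fell, among them mt-Nd2 at -0.65 ± 0.20 and mt-Nd5 at -0.66 ± 0.23. The 7 include mt-Co2 and mt-Nd4l, whose reads are uncertain. Of 12 endothelial genes 5 fell, among them the vascular growth factor receptor genes Flt1 and Kdr at -0.63 ± 0.13 and -0.75 ± 0.21, and of 10 pericyte and smooth muscle genes 5 fell, among them Rgs5 and Myh11 at -0.73 ± 0.14 and -0.94 ± 0.20. Vegfa fell from 263 ± 15.4 to 148 ± 18.1 CPM (SD, n = 3), a log2 fold change of -0.83 ± 0.12. The slow fibre, lymphocyte, mast cell, erythroid and skin lists held no gene that passed by edgeR, among all genes tested or adjusted over the list alone. Of 10 Schwann cell and nerve genes 2 rose and 2 fell, of 12 neuromuscular junction genes 2 rose and 1 fell, of 18 immediate early genes 1 rose, of 15 circadian clock genes 2 fell and of 11 adipocyte genes 2 fell.

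Camera with the preset correlation passed 17 of 31 lists in this comparison, 8 up and 9 down, none of which passed with an estimated correlation, and fry passed 17. For cell division, macrophages and matrix the camera adjusted p was 5.11e-26, 1.62e-17 and 2.12e-13 with the preset correlation and 0.337, 0.417 and 0.417 with an estimated correlation. For glycolysis, oxidative phosphorylation and fast fibres it was 8.48e-07, 1.02e-05 and 6.83e-05 with the preset and 0.562 for each of the 3 with an estimated correlation. The fry adjusted p of these 6 lists was 0.000678, 0.00167, 0.00222, 0.00776, 0.0309 and 0.0204. Leaving out needling replicate 2 lowered the count of changed genes to 2542. Requiring a 2-fold change left 1868 genes, 1739 higher and 129 lower.

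The design also allowed the response to injury to be compared with and without needling. Across 15715 genes, log2 fold changes of injury against saline correlated with those of needling against naive, 2 comparisons that share no library, at Pearson r = 0.803 and Spearman rho = 0.686, with a covariance of 0.546. Genes are not independent replicates, and no p-value was taken across them. Same-numbered injury and needling libraries deviate together, so these comparisons may share chance deviations without sharing a library, which neither the simulated values nor the overlaps of independent lists take in. The mirrored choice, injury against naive with needling against saline, gave r = 0.816. With saline as the shared control r was 0.927 and the covariance 0.479, where simulated unchanged groups against the same control gave 0.53 and 0.0571, leaving 0.422. The 3 saline libraries could not be split into parts of at least 2 libraries, so part of the overlap in the next sentence may come from the shared control. All 658 genes higher in injury than in saline were also higher in needling than in saline, where independent lists would share 122, and 10 of the 11 lower genes were also lower, where independent lists would share 1.21. Against naive muscle, which shares no library with the injury comparison, 656 of the 658 were higher and 8 of the 11 lower in needling, with 152 and 2.09 for independent lists. No gene passed in opposite directions in either pair.

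**Figure D4:**
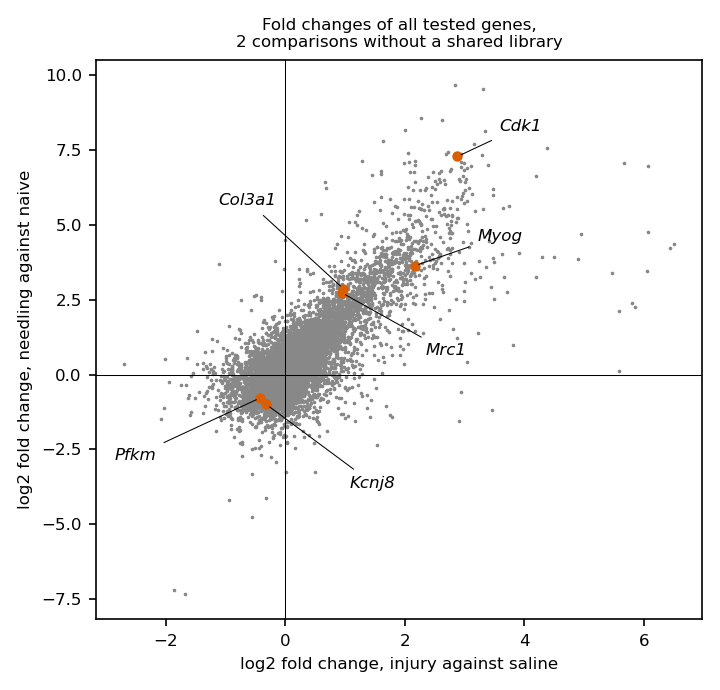
Log2 fold change of each tested gene in injury against saline (horizontal axis) and in needling against naive (vertical axis), 2 comparisons without a shared library. Each grey point is 1 of 15715 genes, and 6 genes are marked. The points follow a rising diagonal with Pearson r = 0.803, on which Cdk1 lies at 2.88 on the horizontal axis.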

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

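The 6-library fits with a replicate block, and the fit that blocks the injury and needling libraries alone within 12, were chosen after the results were seen, as was which genes to name. The alternatives not listed with a value kept each comparison's count within 1.5 times, or at 0.

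For saline against naive, edgeR called 0 genes (1865 at an unadjusted p under 0.05), DESeq2 152 and edgeR without a filter on low counts 3. Leaving out 1 library gave between 0 and 25 genes: 25 without saline replicate 1, 13 without naive replicate 3 and 1 without naive replicate 1. Without naive replicate 1 the heat shock list reversed (adjusted p = 0.0689, range 3.7e-07 to 0.0689 over the left-out libraries), as did Cryab and Hspa8 at log2 differences of 0.0658 and 0.118. The lowest values with a library left out were -1.44 for Cryab and -1.06 for Hspa8. That library's own heat shock transcripts set these signs.

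For injury against saline, 669 genes became 1036 with DESeq2, 1107 with voom and quality weights and 2796 with naive as the control, where the share of higher calls was 68.9% against 98.4%. Leaving out 1 library gave between 0 (injury replicate 1) and 1098 (injury replicate 3), with 74 without injury replicate 2, 103 without saline replicate 1, 161 without saline replicate 2 and 428 without saline replicate 3. Of the 1098 genes 658 were among the 669. Apart from the fewer libraries, the cause was not tested. For needling against saline, 4647 genes became 1868 with the 2-fold minimum. Leaving out 1 library gave between 2542 (needling replicate 2) and 4718 (needling replicate 3).

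For needling against injury, edgeR called 0 genes (2606 at an unadjusted p under 0.05), DESeq2 567, voom with quality weights 911, limma on log2(FPKM + 1) 161 and edgeR without a filter 49. Leaving out 1 library gave 0 or, without needling replicate 3, 1. The cause was not tested. The replicate block over 12 libraries gave 0 here and in saline against naive, 539 in injury against saline and 5058 in needling against saline. The 6-library replicate block gave 3041 genes in needling against injury. With it 20 lists passed camera with the preset correlation and none with an estimated correlation. The block of the injury and needling libraries alone within 12 gave 373 genes. The 6-library block gave 0 genes in injury against saline, 0 in saline against naive and 5350 in needling against saline, where the numbers do not meet the pairing criterion. Neither block moved the counts of saline against naive or needling against saline by over 1.5 times, and the 12-library block did so in no comparison.

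With an estimated correlation camera passed 0 lists in each of the 4 comparisons, where the preset correlation passed 15, 14, 13 and 17. These 0 lists include needling against saline, where every measured macrophage gene rose among all genes tested. A list that did not pass with an estimated correlation is therefore not shown to be unchanged. In needling against injury the adjusted p was then 0.542 for the macrophage, cell division, matrix and oxidative phosphorylation lists, chosen from the 13 after their results were seen. Fry passed 0, 2, 0 and 17 lists.

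The correlation of the injury response with and without needling, 0.803, was 0.927 with the shared saline control. Simulated unchanged groups against that control correlated at 0.53, which is not an amount to subtract from 0.927. With 1 injury or needling library left out, the correlation of 0.803 became 0.746 (without injury replicate 1) to 0.789 (without injury replicate 3). No naive or saline library was left out for this correlation.

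Of the genes named, Cryab and Hspa8 changed sign under these settings. Myf6 and Actc1, which the rule also took in needling against injury, are not among the genes counted next, since they were left out after their sign was seen to change. In injury against saline, 61 of 368 values of these genes under the settings with all libraries were no longer past the threshold, and 143 of 246 with 1 library left out. In needling against saline these were 16 of 459 and 41 of 306. By gene, 16 of the 38 named genes called in injury against saline lost the call under none of the planned settings with all libraries. In needling against saline this held for 42 of 51. In needling against injury 13 of 180 came to pass with all libraries and none of 120 with a library left out. The 6-library replicate block, added after the data were seen, is not counted there, and with it Lyz2, Col3a1 and Pcna were among the named genes that passed. In saline against naive these were 4 of 162 and 1 of 108. On simulated counts a 2-fold change was found for 60 of 100 genes in injury against saline, so a gene that did not pass is not shown to be unchanged.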

Other observations

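The counts of other splits for changed genes, the matchings of replicate numbers, the fibre-share test and the test of naive replicate 1 were chosen after the results they bear on had been seen.

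Each comparison of 3 against 3 libraries allows 10 splits, too few for a share under 0.05. In injury against saline 1 of 10 splits, the real one, gave 669 genes and the highest of the others 0. In needling against saline 1 of 10 gave 4647 and the highest other 0. In saline against naive and in needling against injury the real count was 0, which all 10 of 10 splits reach whatever the data, so these counts say nothing. At an unadjusted p under 0.05 the real splits gave 1865 and 2606 genes and the highest others 1639 and 2240. For gene lists past camera with the preset correlation, the real split passed 15, 14, 13 and 17 lists in the order saline against naive, injury against saline, needling against injury and needling against saline. The highest other splits passed 16, 21, 15 and 18, and 4, 4, 8 and 3 of 10 splits passed at least as many as the real one. A count of lists past this test therefore does not set the real grouping apart in any of the 4 comparisons.

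Of 4 splits that part all 3 same-numbered pairs of injury and needling libraries, 1 gave 3041 genes with the replicate block, the real one, and the others 0. Of 6 ways to match injury with needling libraries, 1 reached a mean correlation of 0.381, the one by replicate number, and the next 0.105. In the 6-library fit the other matchings called at most 471 genes. These are too few splits and matchings for a share under 0.05. A shared day or batch of same-numbered samples, which the labels do not mention, was not tested and may lie behind the 1 of 6, as may a chance alignment of the replicate numbers.

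Macrophage and cell division genes lay higher in needling than in injury muscle. A lower share of muscle fibre RNA would raise the markers of all other cells alike. The macrophage score minus the endothelial score was 1.3 log2 units higher in needling (SD 0.296 in needling and 0.368 in injury, n = 3), which argues against this as the whole cause. After a trend over GC content and gene length was removed from each library, the macrophage score still differed by 0.96 (1.03 before), more than the sum of both SDs (0.312 and 0.486), and the cell division score by 0.874 (0.96 before). The oxidative phosphorylation score differed by -0.424 after and -0.347 before, with overlapping libraries both times. A candidate explanation is that needled muscle was further along the path that injection itself takes. Fold changes of needling minus injury correlated at r = 0.363 across genes with those of saline minus naive, which share no library (covariance 0.0751). Deviations of same-numbered saline and needling libraries correlated at 0.216, 0.176 and 0.0413. These comparisons may therefore share chance deviations without sharing a library. The path of injection itself also rests on a comparison in which 0 genes passed. Genes are not independent replicates. Whether the difference between needling and injury muscle may come from needling, a different extent of injury or a different collection time stays open. The design holds 1 needled group and no needled muscle without bupivacaine.

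Heat shock genes were high in naive replicate 1 alone, with a list score of 8.93 against at most 6.65 in the other 11 libraries. Transcripts chosen after their values were seen were Hspa1b at 3150 CPM (at most 42.5 elsewhere), Dnajb1 at 424 (16.5), Myod1 at 195 (66.6) and Fos at 158 (46.0). Lists also chosen after their values were seen set this library apart from naive replicates 2 and 3. Its neutrophil score was 0.714 against -1.85 and -1.09, and its cytokine score 1.33 against -0.9645 and -0.653. Its embryonic fibre score was 5.125 against 3.78 and 3.65, and its denervation score 5.11 against 4.03 and 4.31. Its slow fibre, tendon and adipocyte scores lay below both. The library is part of the naive control throughout. Without this library 1 gene passed in saline against naive. Leaving out a library also leaves fewer to test, and injury against saline went from 669 genes to 0 without injury replicate 1. The leave-out therefore cannot tell whether naive replicate 1 sets the count of 0 genes in saline against naive. Handling of this sample could not be tested.

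In all 12 libraries the Y-linked gene Ddx3y lay between 72.4 and 110 CPM and Xist at most at 0.25 CPM. Saline replicate 1 held low Myh3, 1.09 CPM, and high Adipoq, 35.9 CPM. Entpd4b, which has near-identical copies and is therefore uncertain, lay at 2, 11 and 11.8 CPM in naive and at most at 0.853 CPM in the other libraries. Each naive library thus lay above every injected library, and the cause was not tested. A difference of the naive samples other than the lack of an injection cannot be told apart here, which limits naive muscle as a control.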
